A study of Mus musculus with 10 samples.

How the data were processed

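Single-cell RNA libraries of whole mouse tumors were analysed from the deposited matrices, 5 labelled 24JK and 5 labelled 24JK-FLT3L, all harvested on day 16. Per the labels' protocols, tumors were cut up, digested with DNase and type IV collagenase, filtered, given an Fc receptor block and stained with fluorochrome-coupled antibodies, and the suspensions were loaded with the 10x Genomics 3′ kit of chemistry version 3.1. The labels name no sort. The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, made by the authors with Cell Ranger on mm10. The version is 3.0.2 per the file headers and 7.1.0 per the submitters' processing notes. The matrices hold all 6794880 barcodes and 31053 genes, and cells were chosen here. The labels number the replicates 1 to 5 in each group but do not say whether these came from separate animals, so p-values measure the spread between these samples.

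Cells were barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. Doublets were scored per library with Scrublet in Scanpy 1.11.5 (Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, scikit-learn 1.9.0). Its automatic threshold called under 0.5% of cells in 8 of 10 libraries, so the highest scores were removed at the expected rate of 0.8% per 1000 cells, 2247 cells in all. Counts were scaled per cell and log transformed, and 2000 variable genes and 30 principal components gave a graph of 15 neighbours, weighted by shared neighbours, which was clustered with the Leiden method (python-igraph 0.11.9, resolution 1, 10 iterations) without batch integration. Clusters were named from fixed markers of 18 lineages: a marker counted if detected in at least 10% of cells with a log2 fold change of at least 1 against the other clusters (10 CPM added), and a name needed 3 markers. T cells were clustered again (1500 genes, 20 components, resolution 2) and named from markers of 4 subsets that reached 30% of the highest cluster's detection.

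Clusters with more markers of a second class, or with low UMIs and no marker in the top 10 genes, stayed unnamed. The largest was cluster 6 (2717 cells, 6.59 ± 0.877% of cells in libraries labelled 24JK and 3.85 ± 1.59% in those labelled 24JK-FLT3L; led by Klra1, Lef1 and Tcf7). The others were cluster 25 (403 cells, 0.749 ± 0.932% and 0.956 ± 0.705%) and cluster 30 (252 cells, 0.479 ± 0.379% and 0.588 ± 0.312%). Unnamed cells made up 7.81 ± 1.54% and 5.39 ± 1.19% (p = 0.0238, exact permutation test). T cell sub-clusters left unnamed were 3 (997 cells, 6.10 ± 1.76% and 6.27 ± 3.99% of T cells) and 19 (336 cells, 2.67 ± 1.67% and 1.54 ± 1.56%). So were 24 (209 cells, 1.76 ± 0.467% and 0.481 ± 0.514%), 25 (190 cells, 1.64 ± 0.968% and 0.681 ± 0.611%) and 26 (39 cells, 0.230 ± 0.148% and 0.329 ± 0.219%).

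Shares were compared with a two-sided exact permutation test of the difference in mean share over the 252 splits of 10 libraries, with Benjamini-Hochberg adjustment over the classes of each family. For genes, counts were summed per library over all cells and per class, with at least 20 cells per library and class and 4 libraries per group. They were tested with edgeR 4.0.16 (R 4.3.3; TMM factors, filterByExpr, robust quasi-likelihood test) at a false discovery rate of 0.05. Log2 fold changes are libraries labelled 24JK-FLT3L minus libraries labelled 24JK, with standard errors; levels are CPM as mean ± SD of the libraries. 24 gene lists were tested with camera (limma 3.58.1, preset correlation 0.01, at least 5 members tested, adjustment over all lists and classes), and again with an estimated correlation and with fry. They covered cDC1, cDC2 and pDC identity, the mature DC program, shared conventional DC genes, DC and myeloid precursors, MHC class I and II presentation and both interferon responses. Further lists held costimulation, chemokines, stem-like T cells, exhaustion, cytotoxicity, macrophage states, proliferation, hypoxia, extracellular matrix, dissociation stress, and erythroid, keratinocyte and skeletal muscle markers. The erythroid and skeletal muscle lists had under 5 members tested and gave no result.

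The genes named are, per class, Flt3l and Flt3, the 10 largest rises and 10 largest falls among called genes with at least 50 CPM in the higher group and no overlap between the groups, and the 4 members of lowest p of each list. The rule leaves out ribosomal protein, mitochondrial, numbered Gm and Rik, immunoglobulin and T cell receptor variable genes. The filters, tests, markers, lists and this rule were chosen before the data were examined. So were the alternatives for UMI and mitochondrial limits, doublets, resolution, normalization (DESeq2 1.42.0 size factors), other tests (DESeq2, limma-voom), low-count filters, thinning, ambient RNA, fixed class weights, the replicate block and single libraries. Chosen after seeing the data were the doublet rate, the ambient window, the T cell resolution and detection rule, the rule for clusters with markers of a second class and the sum of the 4 DC classes with its immune denominator. Added alternatives were removal of copied barcodes, removal of a length and GC trend, removal of genes sharing 3′ sequence, the collagen-high cluster left out and the test of one class against the others. The splits of lists were added too.

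Copied barcodes, with at least 500 UMIs and 300 genes in more than 1 library, were kept in that alternative only where they had the most UMIs, which left 46539 cells. Free RNA was profiled per library from the barcodes ranked after the 20000 highest, down to rank 60000, and scaled by lineage markers to give the share of a gene's counts in a class that it could supply. Transcript lengths and GC content came from GENCODE M21, which matched 31011 of 31053 gene IDs, and their trend was fitted per library with splines of 5 degrees of freedom. Genes sharing at least 50% of the 50-mers in the last 400 nt with another gene are given as uncertain. Pairs of libraries were compared by chi-square over genes, and the lowest value per degree of freedom, 31.9, left no pair within sampling noise. The edgeR test was run on simulated counts with 200 changed genes in the sums and in each class; the share tests were not simulated. Changes of 2-fold were recovered for 67.2% of genes in the sums, 97.01% in T cells, 92.5% in NK cells, 86.6% in CD8 T cells and 85.1% in monocytes and macrophages. The shares were 80.6% in γδ T cells, 77.6% in mesenchymal cells, 77.6% in regulatory T cells, 76.1% in cDC2, 68.7% in CD4 T cells, 67.2% in endothelial cells and 38.8% in neutrophils. In a simulation of monocytes and macrophages with a length trend, edgeR made 508 false calls (74.1% of its calls) without correction and 8 (4.42%) with the trend removed. The gene counts given are without that correction unless it is named. The simulated trend was linear in log length with a set slope that was not fitted to these data, and 200 genes changed. Its shares of false calls therefore do not carry over to the real counts. Camera called 5 of 5 shifted lists and 0 others in a simulation of monocytes and macrophages. Genes were drawn independently there and lists at random, so it cannot test whether the preset correlation holds for these lists.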

Results

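Whole tumors of the transplantable mouse sarcoma line 24JK were profiled by single-cell RNA sequencing. 5 libraries are labelled 24JK and 5 are labelled 24JK-FLT3L, and all were collected on day 16. FLT3L is the ligand of the receptor Flt3 and a growth factor for dendritic cell (DC) development. The comparison addresses how the cells of a tumor and their transcripts differ between the line and its counterpart labelled with that ligand. Each library held between 69120726 and 116704329 UMIs. The filters left 50614 cells, from 4012 to 7340 per library labelled 24JK and from 4099 to 4957 per library labelled 24JK-FLT3L. Depth per cell differed with the label: the median ran from 4445 to 7579 UMIs per cell in libraries labelled 24JK and from 7778 to 11406 in libraries labelled 24JK-FLT3L. Replicates 1 and 2 labelled 24JK shared 5090 barcodes of at least 500 UMIs and 300 genes, against 29 at most in any other pair of libraries. Both were kept as separate replicates in the main tests, although they hold these barcodes in common. Results without the copies are given for the shares, gene counts and lists that moved. Of 501 calls of named genes 74 were lost without the copies, and only some of these are pointed out below. The 2 groups also carry different series of library names, so that a difference in library batch and the group cannot be told apart here.

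The ligand and its receptor were examined first, as a check of the labels. Flt3l (chromosome 7, 45129788 to 45136432, minus strand, mm10) was lower in mesenchymal cells of the libraries labelled 24JK-FLT3L, at 3.03 ± 0.276 against 3.92 ± 0.276 counts per 1e6 UMIs (CPM; SD, n = 5 each). Its log2 fold change was -0.44 ± 0.10 (SE; adjusted p = 0.0108, edgeR's quasi-likelihood test). Its values in replicates 1 to 5 were 3.99, 3.99, 3.78, 4.30 and 3.56 CPM in the libraries labelled 24JK and 3.27, 3.01, 2.59, 3.26 and 3.03 CPM in those labelled 24JK-FLT3L. Over all cells it stood at 8.86 ± 1.23 and 6.76 ± 1.82 CPM, a log2 fold change of -0.50 ± 0.16 that missed the threshold (adjusted p = 0.0547). That fall passed with DESeq2 (adjusted p = 0.0219), limma-voom (0.0396) and doublets kept (0.0476), and without replicate 1 of 24JK (0.0463) or of 24JK-FLT3L (0.00247). In NK cells it was higher in every library labelled 24JK-FLT3L (23.3 ± 2.40 and 32.0 ± 4.19 CPM, 0.31 ± 0.16), but did not pass the test (adjusted p = 0.256), and T cells had 23.14 ± 3.67 and 22.97 ± 4.72 CPM (adjusted p = 0.634). Levels in these classes exceed those in mesenchymal cells, so the value over all cells also moves with the class shares given below. A 3′ assay can miss an introduced gene that lacks the native 3′ end, so these values do not settle the labels, and every direction given here is that of the labels as deposited. Flt3 (chromosome 5, 147330741 to 147400489, minus strand), the receptor that marks DCs and their precursors, fell from 7.55 ± 2.12 to 1.45 ± 0.506 CPM over all cells (log2 fold change -2.49 ± 0.25, adjusted p = 0.000504). Within type 2 conventional DCs (cDC2) it did not pass the test, with 36.5 ± 8.14 and 28.3 ± 4.92 CPM (adjusted p = 0.142).

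DCs made up a smaller share of the libraries labelled 24JK-FLT3L, in total and in each conventional or mature subset. The 4 DC classes together took 8.85 ± 1.06% of cells in the libraries labelled 24JK (range 7.30 to 9.86%) and 2.54 ± 0.216% in those labelled 24JK-FLT3L (range 2.32 to 2.88%). The difference had p = 0.00794 in a two-sided exact permutation test, the smallest p that 5 libraries against 5 allow. The sum was formed after the data had been seen. Type 1 conventional DCs (cDC1), which cross-present antigen to CD8 T cells, carry Xcr1 and Clec9a. They fell from 1.67 ± 0.438% to 0.189 ± 0.0848% of cells, a ratio of 8.83. cDC2, which carry Cd209a, fell from 4.14 ± 0.389% to 1.54 ± 0.362%. Mature regulatory DCs (mregDC), the Ccr7-expressing form that migrates to lymph nodes, fell from 2.45 ± 0.951% to 0.449 ± 0.106%. All 3 differences had adjusted p = 0.0190 over the classes compared (exact permutation test, n = 5 each), and the 5 libraries of one label lay wholly below those of the other. Plasmacytoid DCs (pDC), the DC type that secretes type I interferon, stood at 0.599 ± 0.0544% and 0.356 ± 0.210%, which missed the threshold (adjusted p = 0.0952, exact permutation test). Among DCs alone the cDC1 share fell from 18.9 ± 4.21% to 7.31 ± 2.63% (adjusted p = 0.0317, exact permutation test). The other subsets missed the threshold in that exact permutation test. cDC2 stood at 47.1 ± 5.57% and 60.4 ± 10.9% of DCs and mregDC at 27.2 ± 8.57% and 17.8 ± 4.59% (adjusted p = 0.0847 each, exact permutation test). For pDC the values were 6.82 ± 0.805% and 14.5 ± 9.25% (adjusted p = 0.159, exact permutation test). The cDC2 share of all cells missed it with at most 5% mitochondrial UMIs (adjusted p = 0.0635, exact permutation test). With that limit the higher cDC2 share among DCs passed (adjusted p = 0.0318, exact permutation test). An edgeR test of cell counts called the lower mregDC share (adjusted p = 0.0419) and the higher pDC share (adjusted p = 0.0137) among DCs. Without 24JK-FLT3L replicate 1 the lower pDC share (adjusted p = 0.0238) and the higher cDC2 share among DCs (adjusted p = 0.0159) passed the exact permutation test.

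Natural killer (NK) cells also made up a smaller share, and endothelial cells and the monocyte/macrophage class a larger one. NK cells fell from 9.58 ± 2.22% to 5.70 ± 1.07% and endothelial cells rose from 0.509 ± 0.118% to 0.848 ± 0.0313% (adjusted p = 0.0190 each, exact permutation test, n = 5 each). Monocytes and macrophages rose from 20.4 ± 1.61% to 25.6 ± 3.49% (adjusted p = 0.0476), and among immune cells from 27.3 ± 1.73% to 40.2 ± 8.53% (adjusted p = 0.0357, exact permutation test). The other classes missed the threshold. T cells stood at 34.3 ± 2.28% and 29.3 ± 10.5% (adjusted p = 0.413, exact permutation test). Mesenchymal cells, a class that can hold sarcoma cells and fibroblasts, stood at 16.8 ± 3.62% and 28.5 ± 12.3% (adjusted p = 0.131, exact permutation test). Neutrophils (1.17 ± 0.858% and 1.65 ± 1.08%), B cells (0.478 ± 0.269% and 0.349 ± 0.208%) and keratinocytes (0.0653% and 0.153%) had adjusted p = 0.511, 0.476 and 0.603 in the exact permutation test. The NK call ended with the copied barcodes removed (adjusted p = 0.0635, exact permutation test), with at least 2000 UMIs per cell (0.122) and among immune cells (0.0571). The monocyte/macrophage call ended with the copies removed (0.0571), at 5% mitochondrial UMIs (0.109), with the edgeR test of cell counts (0.0817), without any of 24JK replicates 1 to 4 (0.0952 each) and without 24JK-FLT3L replicate 3 or 5 (0.0635 each). Without 24JK-FLT3L replicate 1 the lower T cell share (-9.10 percentage points) and the higher mesenchymal share (16.4 points) passed at 0.0238.

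**Figure D1:**
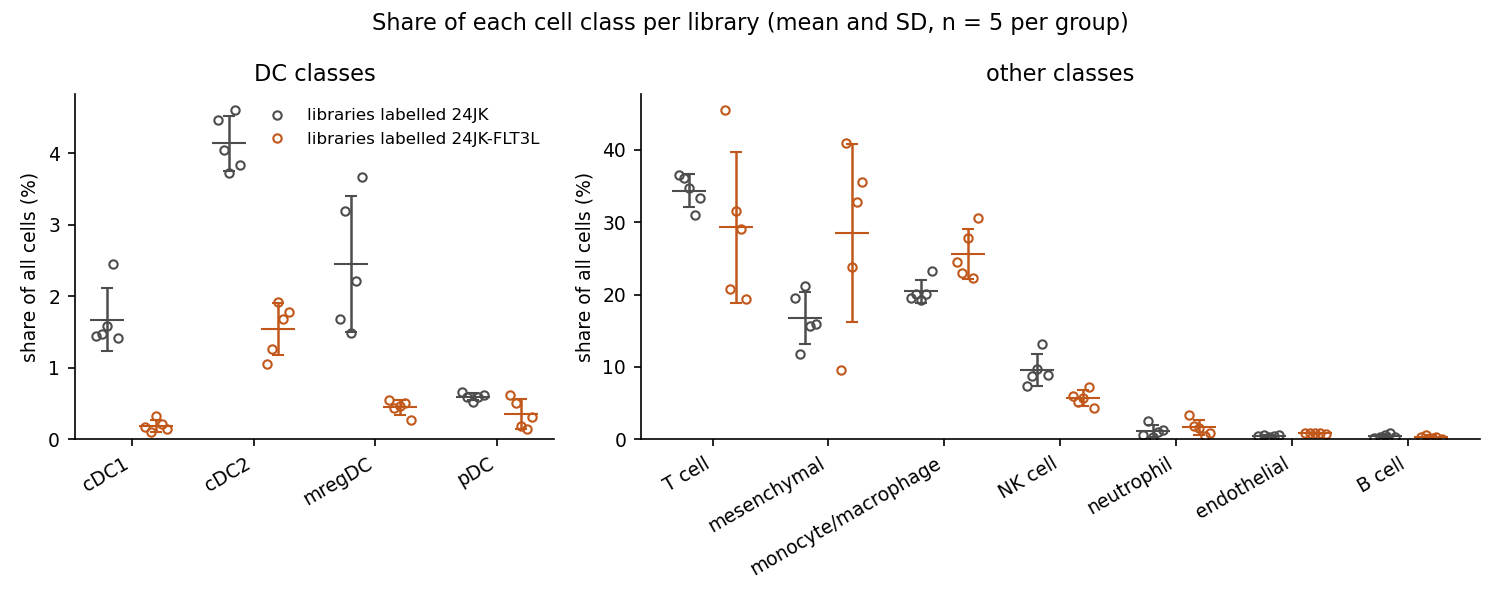
Share of all cells in each class in percent, the 4 DC classes on the left and 7 other classes on the right, with 1 circle per library and the mean (dash) and SD (bar) of the 5 libraries labelled 24JK (grey) and the 5 labelled 24JK-FLT3L (orange). cDC1 lie at 1.67 ± 0.438% and 0.189 ± 0.0848%, cDC2 at 4.14 ± 0.389% and 1.54 ± 0.362%, and NK cells at 9.58 ± 2.22% and 5.70 ± 1.07%.

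Among T cells, conventional CD4 cells made up a smaller share in the libraries labelled 24JK-FLT3L, at 4.56 ± 0.988% against 8.03 ± 1.32% (adjusted p = 0.0317, exact permutation test, n = 5 each). CD8 T cells, the cytotoxic lineage, stood at 63.2 ± 4.65% in libraries labelled 24JK and 75.0 ± 7.92% in those labelled 24JK-FLT3L, a difference that missed the threshold (adjusted p = 0.0635, exact permutation test). Regulatory T cells, marked by Foxp3 (14.01 ± 3.31% and 8.67 ± 4.35%, adjusted p = 0.106), and γδ T cells (2.38 ± 0.430% and 2.44 ± 1.47%, adjusted p = 0.952) did not differ by that test. T cell clusters that stayed unnamed held 12.4 ± 1.45% and 9.30 ± 4.91% of T cells. The CD4 call ended with doublets kept (-0.0134 points, adjusted p = 0.944), with the copies removed (0.0741), at 2000 UMIs or 5% mitochondrial UMIs (0.0952 each) and without 24JK-FLT3L replicate 2, 3 or 4 (0.0635 each). The CD8 difference passed at cluster resolution 2 (0.0159), with 500 UMIs or with doublets kept (0.0317 each) and, as did the lower regulatory T share (-6.75 points), without 24JK-FLT3L replicate 5 (0.0106 each, exact permutation test).

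Summed over all cells of a library, 2736 of 15662 genes differed, 1545 higher and 1191 lower in the libraries labelled 24JK-FLT3L (false discovery rate 0.05, edgeR, n = 5 each). The largest rises among abundant genes were those of the linker histone Hist1h1b (83.2 ± 23.7 to 340 ± 62.2 CPM, log2 fold change 1.93 ± 0.19, adjusted p = 0.000424), the nuclear envelope protein Syne2 (1.12 ± 0.24) and the matrix proteoglycan Vcan (1.02 ± 0.09), which is also a monocyte marker. Next came the ubiquitin ligase Nedd4 (0.99), the cell division genes Anln (0.94) and Cenpe (0.88), the cytoskeletal linker Dst (0.92), the helicase Dhx9 (0.87) and the membrane repair gene Myof (0.86). The largest falls were those of the chemokine receptor and mregDC marker Ccr7 (88.1 ± 30.7 to 27.9 ± 11.5 CPM, -1.77 ± 0.29, adjusted p = 0.00335) and of Cst3 (-1.22 ± 0.12, adjusted p = 0.00043), a protease inhibitor abundant in DCs. They were followed by the monocyte marker Ms4a4c (-1.21), Napsa (-1.03), the interferon-induced genes Rsad2 (-0.96) and Ube2l6 (-0.86) and the T cell-attracting chemokine Cxcl10 (-0.80 ± 0.14, adjusted p = 0.0046). In each of these genes the 5 libraries of one label lay above all 5 of the other, as the naming rule required. Hist1h1e, Hist1h2ap and Tmsb10 met the same rule, but share sequence with other genes at the 3′ end and are uncertain. A limma test of 6 classes at fixed weights, 62.1% of it mesenchymal cells, called 84.7% of its genes higher (3397 of 4010), against 56.5% by edgeR in the sums. The test, the weights and the classes entered all differ between these values. Without single libraries the count was 1470 (24JK replicate 4), 1609 (24JK replicate 5), 6107 (24JK-FLT3L replicate 1), 1502 (24JK-FLT3L replicate 4) and 1599 (24JK-FLT3L replicate 5).

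The DC gene lists fell in the summed libraries, together with the lower DC shares above. Of the cDC1 identity genes 11 of 15 fell (13 adjusted over the list alone; median log2 fold change -0.76). Among them were Clec9a, a receptor for dead cells (10.9 ± 2.66 to 3.52 ± 0.602 CPM, -1.74 ± 0.18, adjusted p = 0.000574), Itgae (-1.73), Snx22 (-1.83) and Sept3 (-2.65 ± 0.31). Of the mature DC program 12 of 19 fell (17 adjusted over the list alone; median -1.10). They included the interleukin 12 subunit Il12b (24.3 ± 8.52 to 4.83 ± 2.92 CPM, -2.45 ± 0.40, adjusted p = 0.00316), Ccl22 (-2.20), Nudt17 (-1.70) and Cacnb3 (-1.11). The cDC2 identity list had 5 of 13 members lower (9 over the list alone; Cd209a -1.79, H2-DMb2 -1.55, Ffar2 -1.52, Cbfa2t3 -1.11). The pDC identity list had 4 of 13 lower (7 over the list alone; Cd300c -1.74, Pacsin1 -1.06). The shared conventional DC genes had 9 of 17 lower (13 over the list alone; H2-Oa -1.67, the inhibitory receptor Btla -1.79, Bcl11a -1.44). All 5 lists passed camera, with adjusted p from 1.59e-08 to 0.000526, and none with an estimated correlation (adjusted p = 0.425 to 0.483). The DC and myeloid precursor list did not pass (1 of 10 lower, adjusted p = 0.485), and its median (0.06) and mean (-0.37) differed in sign.

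Antigen presentation, priming and chemokine lists were also lower in the sums, in which DCs and NK cells made up a smaller share. MHC class II presentation had 4 of 13 members lower (6 adjusted over the list alone; adjusted p = 2.22e-05), with H2-Ob (-2.07 ± 0.19) and H2-Oa, which modulate peptide loading, in front. Within cDC2 its median was -0.22, with 1 of 13 called (7 over the list alone; adjusted p = 0.0181, and adjusted p = 0.524 with an estimated correlation), and it did not pass with a length and GC trend removed (adjusted p = 0.287). In the sums MHC class I presentation was mixed, with 10 members lower and 2 higher of 18 (15 and 2 over the list alone; adjusted p = 0.000651). The peptide-loading gene Tapbp (-0.43) and the immunoproteasome subunit Psmb10 (-0.45) fell, and the trimming protease Erap1 (0.46) and the chaperone Pdia3 (0.50) rose. The interferon-gamma response list had 8 of 19 lower (9 over the list alone; adjusted p = 1.78e-05; Socs1 -0.85, Igtp -0.69). Costimulation and T cell priming had 6 of 14 lower (6 lower and 1 higher over the list alone; adjusted p = 0.00313; Cd40 -0.63, Il15 -0.66). T cell-attracting chemokines had 4 of 9 lower (adjusted p = 0.00041; Ccl17 -2.21). Cxcl9 (-0.73), a member of the interferon-gamma and chemokine lists, missed the threshold with the copies removed (adjusted p = 0.054). Stem-like T cell genes had 3 of 16 lower (4 over the list alone; adjusted p = 0.000488), among them Tcf7, a transcription factor of stem-like T cells (-0.53, adjusted p = 0.0287), which missed the threshold with the copies removed (adjusted p = 0.0815). Unnamed cluster 6 has Lef1, Satb1 and Tcf7 of this list among its leading genes. It held 6.59 ± 0.877% of cells in libraries labelled 24JK and 3.85 ± 1.59% in those labelled 24JK-FLT3L. T and NK cytotoxicity had 1 of 15 lower (adjusted p = 0.00554), the NK marker Gzma (-1.39). With an estimated correlation none of these passed (adjusted p = 0.483 to 0.583). Proliferation (3 of 20 higher; Mki67 0.78, Top2a 0.73, Cenpf 0.64) and extracellular matrix genes (3 of 21 higher and 5 over the list alone; Col4a1 0.69, Col4a2 0.61, Mmp14 0.55) did not pass (adjusted p = 0.117 each). Nor did exhaustion (0 of 17, adjusted p = 0.0624), hypoxia (2 higher and 2 lower of 17, 0.856), inflammatory macrophage (1 of 13, 0.406), dissociation stress (1 of 16, 0.261; Jund -0.47) and keratinocyte genes (0 of 5, 0.906). Alternatively activated macrophage genes did not pass either (adjusted p = 0.906). Mrc1, the mannose receptor (0.98), and Vegfa (0.39) rose, Retnla fell (-2.15), and the list's median (0.05) and mean (-0.04) differed in sign.

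**Figure D2:**
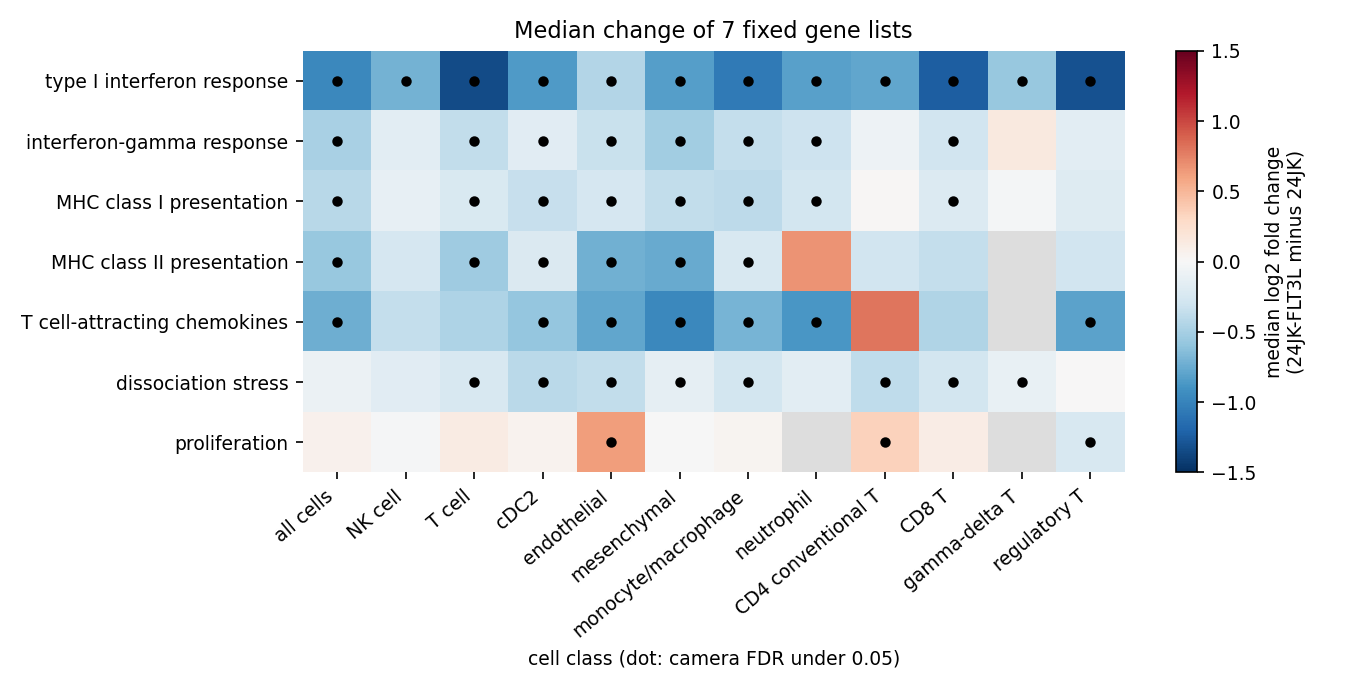
Median log2 fold change (color, libraries labelled 24JK-FLT3L minus libraries labelled 24JK) of 7 of the fixed gene lists in all cells and in each class tested, with grey where under 5 members were tested and a dot where camera passed a false discovery rate of 0.05. The type I interferon response is below 0 with a dot in all 12 columns, at -0.96 over all cells and -1.06 in monocytes and macrophages.

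Type I interferon response genes, which are induced by interferon alpha and beta and encode antiviral proteins, were lower in the libraries labelled 24JK-FLT3L in the summed libraries and in each of the 11 classes tested. In the sums 18 of 20 members fell (18 adjusted over the list alone; median -0.96, adjusted p = 3.84e-11), with Oas1a (21.1 ± 4.94 to 7.94 ± 2.87 CPM, -1.52 ± 0.22, adjusted p = 0.00197), Oasl1 (-1.46) and Usp18 (-1.44). Monocytes and macrophages had 19 of 20 lower (20 over the list alone; median -1.06, adjusted p = 4.72e-17), T cells 17 of 20 (19; -1.34, 1.04e-11) and mesenchymal cells 11 of 20 (17; -0.82, 4.47e-07). The counts were 8 of 14 in NK cells (9; -0.70, 1.55e-08), 3 of 19 in cDC2 (8; -0.85, 1.71e-08), 5 of 19 in endothelial cells (6; -0.44, 0.000176) and 4 of 16 in neutrophils (11; -0.82, 1.61e-12). Among T cell subsets they were 13 of 19 in CD8 (15; -1.24, 3.21e-11), 12 of 17 in regulatory (13; -1.31, 3.1e-15), 6 of 11 in CD4 (8; -0.78, 8.13e-07) and 1 of 7 in γδ T cells (3; -0.57, 0.013). Irf7, the transcription factor that amplifies this response, fell in monocytes and macrophages (315 ± 40.5 to 117 ± 34.3 CPM, -1.52 ± 0.17, adjusted p = 0.000404) and NK cells (-1.36 ± 0.12, adjusted p = 3.19e-09). It also fell in T cells (-1.37), regulatory T cells (-1.58), mesenchymal cells (-1.46) and endothelial cells (-1.31). With an estimated correlation the list passed in none of the 12 (adjusted p = 0.180 to 0.524). Fry did not call it in mesenchymal cells (adjusted p = 0.0531), cDC2 (adjusted p = 0.0681), endothelial cells (adjusted p = 0.113) or γδ T cells (adjusted p = 0.146). With each library left out in turn camera called it in 11 or 12 of the 12 fits, and without 24JK replicate 2 no list was called in γδ T cells.

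In monocytes and macrophages 1927 of 11417 genes differed, 1119 higher and 808 lower. Mrc1 rose from 364 ± 56.4 to 754 ± 160 CPM (0.97 ± 0.15, adjusted p = 0.00161). It rose together with the ubiquitin ligase Wwp1 (0.82), the transcription regulators Btaf1 (0.81) and Jdp2 (0.76), Dhx9 (0.79), the cytoskeletal linker Macf1 (0.79) and Eprs (0.76). Ly6c2, a marker of inflammatory monocytes, fell from 414 ± 130 to 152 ± 40.5 CPM (-1.54 ± 0.23, adjusted p = 0.00174), and with it Oasl1 (-1.51), Ly6i (-1.46), Ifit1 (-1.41), Oas3 (-1.30), Ifit3 (-1.30) and Retnla (-2.15). The class pools several clusters, among them cluster 1, led by Ly6i and Thbs1, and cluster 19, led by Mmp12 and Retnla. Whether their mix differed between the labels was not tested, so such a difference is not separated from a change within cells. Ccl5 (-1.50, adjusted p = 0.021) missed the threshold with the copies removed (adjusted p = 0.075). Interferon-gamma response genes had 9 of 18 lower (12 adjusted over the list alone; adjusted p = 8.19e-06; Ly6a -0.91, Socs1 -0.98, Igtp -0.72). MHC class I presentation had 15 lower and 2 higher of 18 (adjusted p = 1.49e-05; Tap1 -0.44, Tapbp -0.49, Erap1 0.51, Pdia3 0.44). T cell-attracting chemokines had 5 of 9 lower (6 over the list alone; adjusted p = 0.000412; Cxcl9 -0.58, Ccl4 -0.70, Ccl3 -0.56). With an estimated correlation these lists had adjusted p = 0.483, 0.267 and 0.294. Costimulatory genes went both ways, with Cd40 (-0.74) and Il15 (-0.61) lower and Cd80 (0.43) higher. The mature DC program, whose members mark another class, had 7 of 16 lower (9 over the list alone; adjusted p = 0.000123, and adjusted p = 0.483 with an estimated correlation). Hist1h1b (2.12) rose in this class too, with 36% of its counts in one group attributable to free RNA.

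T cells had 1814 of 11314 genes changed, 1089 higher and 725 lower. Havcr2, the inhibitory receptor TIM-3, rose from 80.1 ± 7.01 to 154 ± 20.03 CPM (0.87 ± 0.09, adjusted p = 8.24e-05). Entpd1 (0.39), the peptidase Dpp4 (0.94), the division genes Mki67 (0.88), Hmmr (0.92) and Ckap5 (0.82) and the histones Hist1h1b (1.93), Hist2h2ac (1.21) and Hist1h4d (1.08) rose as well. Interferon-induced genes led the falls: Ifi27l2a (-1.90), Ifit1 (-1.85), Rtp4 (-1.77), Isg20 (-1.18) and Iigp1 (-1.10), with Rsad2 (-2.04) and Oas1a (-2.08) at lower levels. Foxp3, the factor that defines regulatory T cells, fell from 68.5 ± 12.9 to 30.6 ± 11.9 CPM (-1.29 ± 0.27, adjusted p = 0.0118). Izumo1r (-1.04) and the checkpoint receptor Ctla4 (-0.60) fell too, in a class whose regulatory T share stood at 14.01% and 8.67%. Tcf7 fell from 31.3 ± 4.98 to 20.7 ± 4.67 CPM (-0.69 ± 0.16, adjusted p = 0.0118). It was 1 of 5 stem-like genes lower of 16, and the list did not pass (adjusted p = 0.0978). Slamf6 (-0.57, adjusted p = 0.0115) was another, but missed the threshold with the copies removed (adjusted p = 0.075). Unnamed cluster 6, with 9 T cell and 6 NK cell markers and Lef1 and Tcf7 among its leading genes, lay outside this class. It held 6.59 ± 0.877% of cells in libraries labelled 24JK and 3.85 ± 1.59% in those labelled 24JK-FLT3L. The exhaustion list, with 3 of 17 higher and 2 lower, did not pass (adjusted p = 0.453). Dissociation stress genes passed (4 of 16 lower, 5 adjusted over the list alone; adjusted p = 0.000488, and adjusted p = 0.483 with an estimated correlation), with Jund at -0.64. Interferon-gamma response genes passed as well (5 of 18 lower, 7 over the list alone; adjusted p = 0.000287, and adjusted p = 0.536 with an estimated correlation). The count of changed genes was 1202 without 24JK replicate 4 and 1199 without 24JK-FLT3L replicate 4.

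CD8 T cells alone showed 1086 changed genes of 10497, 726 higher and 360 lower. Havcr2 rose from 89.3 ± 7.80 to 166 ± 21.7 CPM (0.80 ± 0.09, adjusted p = 0.000297), with Ckap5 (0.83), the endocytic receptor Ly75 (0.79), Macf1 (0.76), Cep350 (0.73), Entpd1 (0.39) and Dpp4 (0.89). Tcf7 fell from 22.1 ± 3.34 to 13.8 ± 3.42 CPM (-0.82 ± 0.17, adjusted p = 0.00791), and Ifit1 (-1.85), Isg20 (-1.17), Bst2 (-0.98), Prkca (-0.76), the glucocorticoid-induced gene Tsc22d3 (-0.73), Jund (-0.65) and Ifi35 (-0.59) fell as well. Different clusters had the largest mean share in the 2 groups, but these shares varied widely between libraries and were not tested. Clustering was done without batch integration, so a split of clusters by library or batch is not excluded. Sub-cluster 1, led by Osgin1 and Ly6c2, was the largest in libraries labelled 24JK (9.48 ± 6.85% of T cells, and 2.14 ± 2.04% in those labelled 24JK-FLT3L). Sub-cluster 2, led by Osgin1 and Susd1, was the largest in libraries labelled 24JK-FLT3L (11.3 ± 8.75%, and 2.09 ± 0.743% in those labelled 24JK). The count was 683 without 24JK replicate 4 and 701 without 24JK replicate 5.

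Regulatory T cells had 740 of 7836 genes changed (437 higher, 303 lower), conventional CD4 T cells 165 of 5334 (70 higher, 95 lower) and γδ T cells 25 of 2103 (9 higher, 16 lower, 5 libraries against 4). In regulatory T cells Havcr2 (0.80), Hist2h2ac (1.31) and Top2b (0.91) rose, and Ifi27l2a (-1.18, adjusted p = 7.71e-10), Ifit1 (-1.84), Rtp4 (-1.37), Ifi206 (-1.32) and Isg15 (-1.09) fell. Cytotoxicity genes were lower there (4 of 11, 7 adjusted over the list alone; adjusted p = 6.8e-06, and adjusted p = 0.234 with an estimated correlation). They included the NK marker Prf1 (-1.72), Fasl (-1.36) and Ccl5 (-0.95), beside the CD8 marker Cd8a (-2.22). A contribution of CD8 T cells to the regulatory T sums was not tested and stays open for these genes. Proliferation genes were lower in this subset (7 of 20, 9 over the list alone; adjusted p = 0.0131, and adjusted p = 0.632 with an estimated correlation), among them the mitotic genes Ccnb2 (-0.99, adjusted p = 9.48e-05), Ube2c (-1.04) and Aurka (-1.30). In CD4 cells the list was higher (1 of 11, median 0.35, adjusted p = 0.0347, and adjusted p = 0.536 with an estimated correlation). The called member was Mki67 (1.74, adjusted p = 0.00515). CD4 cells also raised the integrin Itgb1 (387 to 818 CPM, 0.99 ± 0.12, adjusted p = 1.86e-06), Ahnak (0.95) and Rad50 (1.14), and lowered Irf7 (-1.65), Oasl2 (-2.08), Rtp4 (-1.31), Irgm1 (-1.001), Ifi47 (-0.85) and the RNA decay factor Zfp36 (-1.01). In γδ cells Stag2 (1.31) and Ahnak (0.80) rose and Isg15 (-0.81) fell, while Top2b, Lmna and Jund missed the threshold with the copies removed. Counts without single libraries were 493 (24JK replicate 4) and 443 (24JK-FLT3L replicate 4) in regulatory, and 101 (24JK replicate 3) in CD4 cells, which had 98 with the copies removed. In γδ cells they were 16 (24JK replicate 3), 16 (24JK-FLT3L replicate 1), 14 (24JK-FLT3L replicate 2) and 11 (24JK-FLT3L replicate 4).

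Mesenchymal cells had the most changed genes of any class, 3038 of 14181, with 2209 higher and 829 lower (72.7% higher; 2296 of 3736, or 61.5%, by DESeq2). Their sums were also the deepest of any class, 2.23e+07 to 7.25e+07 UMIs per library, against 448151 to 1.56e+06 in endothelial cells. Depth was not equalised between classes, so the ranking does not compare the size of their changes. Hist1h1b rose from 95.1 ± 26.7 to 377 ± 50.9 CPM (1.92 ± 0.17, adjusted p = 8.35e-05) and the integrin Itgb1 from 243 ± 23.7 to 477 ± 35.2 CPM (0.91 ± 0.07, adjusted p = 3e-05). The transferrin receptor Tfrc (0.90), Dhx9 (0.98), Syne2 (0.97), the tankyrase Tnks (0.92), Lrpprc (0.89) and the monocyte marker Vcan (0.93) rose. The division genes Mki67 (0.85), Top2a (0.61), Cenpf (0.50) and Plk1 (0.40), the basement membrane collagens Col4a1 (0.42) and Col4a2 (0.35), the matrix protease Mmp14 (0.42) and the hypoxia-induced genes Vegfa (0.53) and Ero1l (0.52) rose too, although none of their lists passed. Rsad2 (-0.91), the metallothionein Mt1 (-0.65), the respiratory chain subunit Atp5k (-0.63), Socs1 (-0.59), Psmb10 (-0.56) and Tomm7 (-0.52) fell, as did Cxcl10 (713 ± 122 to 412 ± 119 CPM, -0.86 ± 0.21, adjusted p = 0.0158) and Ccl2 (-0.38). Interferon-gamma response genes passed (4 of 19 lower, 6 adjusted over the list alone; adjusted p = 0.000132, and adjusted p = 0.568 with an estimated correlation), with Igtp at -0.73. So did MHC class I presentation (7 lower and 2 higher of 18, 9 and 2 over the list alone; adjusted p = 0.00198, and adjusted p = 0.583 with an estimated correlation). The cDC2 identity, mature DC, shared conventional DC, MHC class II and cytotoxicity lists were called lower here as well (cytotoxicity 5 of 15, 9 over the list alone; adjusted p = 2.9e-05), and the cDC1 and pDC identity lists were not. With an estimated correlation the 5 lists had adjusted p = 0.495, 0.515, 0.524, 0.483 and 0.498. The members that led them belong to other cell types, and free RNA could supply much of their counts (up to 49% for Cd74).

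Endothelial cells, NK cells, cDC2 and neutrophils were tested in the same way. In endothelial cells 640 of 8291 genes differed (381 higher, 259 lower). The cytokine signal inhibitors Socs1 (210 ± 46.0 to 83.5 ± 18.3 CPM, -1.49 ± 0.18, adjusted p = 0.000776) and Socs3 (-0.73) fell. The chromosome condensation gene Smc2 (1.31), Myh10 (1.38), Prc1 (2.16) and Mmp14 (0.56) rose. Proliferation genes were higher (3 of 20, 9 adjusted over the list alone; adjusted p = 1.78e-05, and adjusted p = 0.425 with an estimated correlation), but Cenpf (1.63) and Top2a (1.28) missed the threshold with the copies removed. NK cells had 667 of 7649 genes changed (369 higher, 298 lower). The nuclear lamin Lmna (332 ± 67.9 to 125 ± 21.9 CPM, -1.52 ± 0.14, adjusted p = 8.82e-07), Rgcc (-1.41), Klf4 (-0.99), S1pr1, which governs exit from tissue (-0.88), and Jund (-0.84) fell. The receptors Cd160 (0.62) and Cd244 (0.43) and the granule traffic gene Lyst (0.77) rose. The NK marker Gzma did not pass within NK cells (-0.40, adjusted p = 0.189). In cDC2, 692 of 8042 genes differed (437 higher, 255 lower). The cell cycle inhibitor Cdkn1b (81.5 ± 14.1 to 167 ± 14.4 CPM, 0.96 ± 0.12, adjusted p = 6.76e-05), Macf1 (1.00), Dpp4 (0.70), Havcr2 (0.61), the prostaglandin synthase Ptgs2 (0.61) and Cd80 (0.50) rose. Bst2 (-0.85), Impact (-0.84), Jund (-0.78), Tnf (-0.88), Bcl3 (-0.68) and Cd83 (-0.35) fell. MHC class I presentation in cDC2 had 9 members lower and 2 higher of 18 (14 and 3 over the list alone; adjusted p = 0.00221, and adjusted p = 0.535 with an estimated correlation). With a length and GC trend removed, 3 were lower and the list did not pass (adjusted p = 0.0560). Neutrophils, with 4 libraries labelled 24JK against 5, had 10 of 1821 genes changed. Il23a (2.08), a subunit of interleukin 23, rose, and Irf7 (-1.09), Rtp4 (-1.10) and Isg20 (-1.09) fell. cDC1, mregDC, pDC, B cells and keratinocytes had too few cells to be tested.

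Counts of changed genes in these smaller classes moved with the settings and with single libraries. The endothelial count was 107 with at most 5% mitochondrial UMIs, 177 with a length and GC trend removed and 1052 with doublets kept. Endothelial counts were 414 without 24JK replicate 2, 391 without 24JK replicate 4 and 307, 396 and 336 without 24JK-FLT3L replicates 3, 4 and 5. The NK count was 440 without 24JK-FLT3L replicate 3, and the cDC2 counts were 1079, 453 and 433 without 24JK-FLT3L replicates 1, 3 and 5. Neutrophil counts were 3 and 1 without 24JK replicates 2 and 4, and 0 by edgeR without 24JK-FLT3L replicate 2, 3 or 4.

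**Figure D3:**
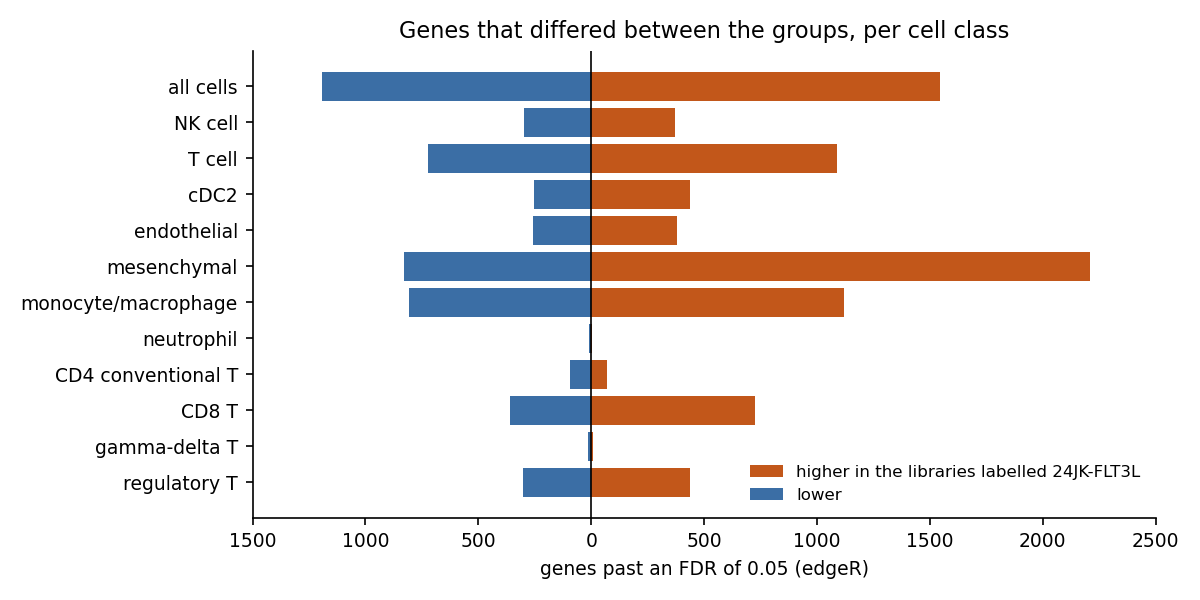
Number of genes higher (bars to the right) and lower (bars to the left) in the libraries labelled 24JK-FLT3L at a false discovery rate of 0.05 by edgeR, over all cells and in each class tested. Mesenchymal cells have 2209 higher and 829 lower, and neutrophils 2 and 8. Summed depth was not equalised between classes.

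Transcript length moved with the label in every class tested. The rank correlation of a gene's fold change with its exonic length, across genes, which are not independent replicates, ran from 0.144 to 0.426 over the 12 fits. Genes higher in the libraries labelled 24JK-FLT3L had a median exonic length of 7138 nt in the sums, against 2893.5 nt for genes lower there. In mesenchymal cells these medians were 7038 and 2563 nt, in monocytes and macrophages 8019 and 2737 nt and in T cells 7312 and 2833 nt. In neutrophils, with 10 changed genes, the order was the other way (2039 and 2632 nt). With a length and GC trend removed from each library, 1795 genes were called in the sums (876 higher, 919 lower), 1117 in monocytes and macrophages (553 and 564) and 349 in NK cells (165 and 184), so that the majority of higher genes was lost in these. Mesenchymal cells kept it (1437 and 570 of 2007), as did T cells (635 and 540 of 1175). Of the 508 calls of named genes 134 missed the threshold. Among those given above were Tcf7, Mrc1, Top2a and Cenpf in the sums, Retnla, Ccl5 and Cd80 in monocytes and macrophages, and Cd8a and Ccl5 in regulatory T cells. Others were Ahnak and Isg15 in γδ T cells, Ccl2 and Cenpf in mesenchymal cells, Cd244 in NK cells and Cd83 and Tnf in cDC2. Prc1, Cenpf and Top2a in endothelial cells and Rtp4 in neutrophils missed it too. The type I interferon list was then called lower in all 12.

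**Figure D4:**
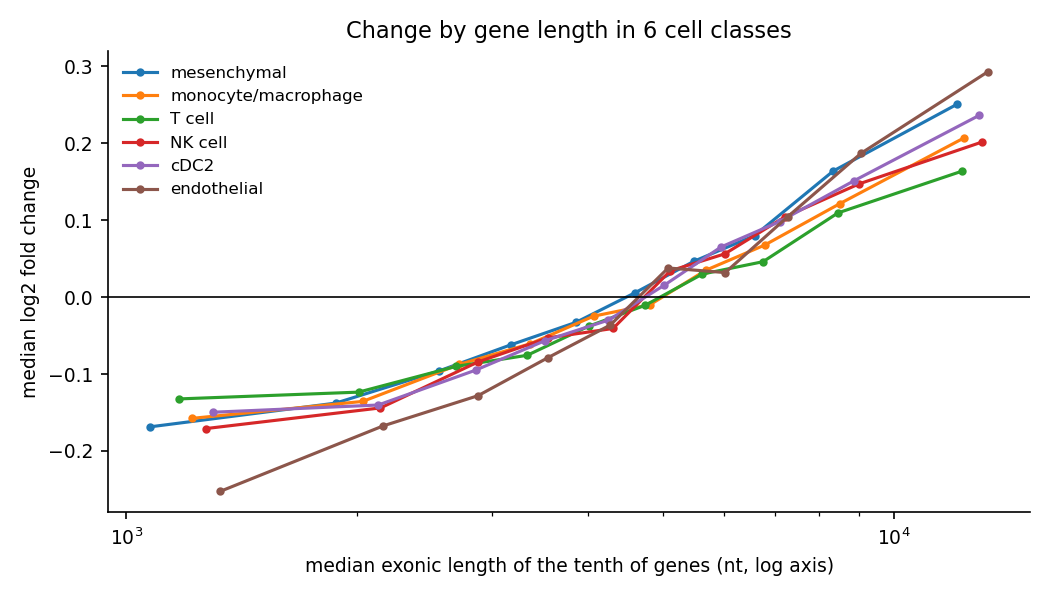
Median log2 fold change (libraries labelled 24JK-FLT3L minus libraries labelled 24JK) in 10 bins of the tested genes ordered by exonic length in nt (log axis), 1 line per class for 6 classes. Fold changes rise with length, and the rank correlation across genes runs from 0.144 to 0.426 over the 12 fits.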

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

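The tests of explanations given here, and the sum of all DCs, were chosen after the results had been seen.

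Of 60 sets of 4 or 5 libraries examined, 5 held a library far from the rest, where chance gives about 1 in 20. 24JK replicate 4 had the highest cDC1 share, 2.45% of cells against 1.42 to 1.58% in the other 4 libraries of its label, and the highest regulatory T share, 19.7% of T cells against 11.5 to 13.6%. 24JK replicate 5 had 23.3% monocytes and macrophages against 19.2 to 20.1%. 24JK-FLT3L replicate 5 had a median of 248 UMIs in barcodes without cells against 63 to 88, and 1496 barcodes over 10% mitochondrial UMIs against 296 to 403. 24JK-FLT3L replicate 1 did not meet the rule behind these counts, but its chi-square per degree of freedom against the other 4 libraries of its label was 223 to 552, where these gave 31.9 to 134 among themselves. It had 9.58% mesenchymal cells against 23.7 to 40.9%, and without it 6107 genes were called over all cells instead of 2736.

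Changes in a class minus the mean change in the other classes passed the test for 6 genes in 3 of 6 classes. The interferon-induced exonuclease gene Isg20 differed by 0.95 (log2) in mesenchymal cells, where its own change of -0.27 did not pass (adjusted p = 0.215), against a mean of -1.22 in the other classes. In monocytes and macrophages the nucleoside enzyme gene Upp1 differed by -1.08 and the mitochondrially encoded mt-Nd4l, mt-Atp8 and mt-Nd5 by 0.62, 0.54 and 0.51, and in NK cells the retinol enzyme gene Dhrs3 by -0.83. In T cells, cDC2 and endothelial cells the same test, run on log2 CPM values, called 0 genes, with 657, 491 and 621 at an unadjusted p under 0.05. No other tool was run on it.

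24JK replicates 1 and 2 shared 5090 barcodes with at least 500 UMIs and 300 genes, where 7.46 would be shared by chance. In 4438 of them replicate 2 had more UMIs, and replicate 1 held a median of 46.0% as many (5th to 95th percentile 43.3 to 47.9%); in the other 652 replicate 2 held 1.58% as many as replicate 1. Profiles of the same barcode correlated at a median r of 0.787 across genes, against 0.514 for other barcodes. With the copies removed, 3661 of 7340 cells left replicate 1 and 142 of 4226 left replicate 2, and all DCs stood at 8.82 ± 1.22% and 2.53 ± 0.223% of cells (p = 0.00794, exact permutation test).

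The lower share of DCs in the libraries labelled 24JK-FLT3L ran against the growth factor in the label. The depth per cell could set such a difference, but it was -6.54 percentage points with at least 2000 UMIs per cell and -7.97 with 500, so the UMI minimum does not account for it. Dilution by mesenchymal cells is excluded as the whole cause by the share among immune cells, which fell by 7.84 points (11.8 ± 1.09% to 3.97 ± 0.591%, p = 0.00794, exact permutation test). An exchange of the group labels stays open. Flt3l in mesenchymal cells had a log2 fold change of -0.44. It stood at 3.56 to 4.30 CPM in libraries labelled 24JK and at 2.59 to 3.27 CPM in those labelled 24JK-FLT3L. Both lie below its levels in T and NK cells, so neither label shows a raised level there. The fall thus decides nothing, and the assay may not capture the introduced gene. In NK cells Flt3l ran with the labels (23.3 and 32.0 CPM, no overlap between libraries) without passing the test (adjusted p = 0.256), and in T cells it stood at 23.14 and 22.97 CPM. A biological difference between tumors of the 2 labels and a difference in library batch also stay open. No test here separates them from the exchange or from each other.

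The lower type I interferon genes in all 12 fits have 2 technical explanations that the tables argue against. After removal of the length and GC trend the list was still called lower in 12 of 12 fits. Free RNA could supply at most a median of 6.77% of the list's counts in the libraries labelled 24JK, where the fall would need at least 26.4%. Chance is not excluded: 5 of 100 splits of the libraries, the real one included, called the list in one direction in 12 fits. The median of the splits was 4. A difference in library batch and a difference between the tumors of the 2 labels stay open as well, and they cannot be told apart here.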

How the results depend on the processing

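The removal of copied barcodes, of a length and GC trend and of genes sharing sequence, the collagen-high cluster left out and the immune denominator of all DCs were chosen after seeing the data; the other settings were not. Shares are given as differences in percentage points, genes as counts past the threshold and lists as counts called by camera; where a count or call moved, the cause was not tested unless fewer genes or libraries entered. The lower share of all DCs kept its direction and its call under every setting but the sign-flip test. In neutrophils, counts thinned to the smallest library gave 1 gene, with 719 genes tested against 1821 in the main fit.

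For the replicate block, same-numbered libraries did not deviate together (0 of 5 pairs with r over 0.1, from -0.669 to -0.103, and 0 libraries correlated best with their own number), so the numbers name samples only. With the block, Flt3l in mesenchymal cells was -0.44 (adjusted p = 0.0569), and the gene counts were 320 over all cells, 558 in CD8 T cells, 1183 in T cells, 40 in γδ T cells, 1945 in mesenchymal cells and 1 in neutrophils. In NK cells 4 lists were called. The exact sign-flip test of same-numbered pairs cannot go below p = 0.0625. Its differences were -6.32 for all DCs, -1.48 for cDC1, -2.59 for cDC2, -1.996 for mregDC and -3.88 for NK cells. They were 0.339 for endothelial cells, 5.17 for monocytes and macrophages, -11.6 for cDC1 among DCs and -3.47 for CD4 among T cells.

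Filters on cells moved the following. With at least 2000 UMIs the CD4 share was -2.56 and the NK share -2.81, and with 500 UMIs the CD8 share was 15.3. With at most 5% mitochondrial UMIs the shares were -2.54 for CD4, -2.75 for cDC2, 5.78 for monocytes and macrophages and 16.7 for cDC2 among DCs, which gained a call. The counts were 350 in NK cells, 107 in endothelial cells and 1272 in monocytes and macrophages. With doublets kept the CD4 share was -0.0134 and the CD8 share 19.8, Flt3l over all cells was -0.51, and the counts were 43 in CD4 T cells and 1052 in endothelial cells. Leiden resolution 2 gave a CD8 share of 13.01. With copied barcodes removed the shares were -2.91 for CD4, -0.116 for γδ, which turned its sign, -3.57 for NK and 5.05 for monocytes and macrophages. The counts were 98 in CD4 T cells and 4 in neutrophils, and 1 list was called in γδ T cells. An immune denominator gave -3.93 for NK cells. The edgeR test of cell counts gave 5.17 for monocytes and macrophages, -9.32 for mregDC among DCs and 7.68 for pDC among DCs, the first losing and the others gaining a call.

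Tests and scaling moved others. DESeq2 gave -0.49 for Flt3l over all cells and 20 genes in neutrophils, and limma-voom gave -0.53 for Flt3l. Thinned counts gave 424 genes in NK cells, 360 in cDC2, 365 in endothelial cells, 1 in neutrophils and 378 in regulatory T cells. With limma on 6 classes at fixed weights, where the test changed as well, Cbfa2t3 (0.068) and H2-Eb2 (0.13) turned their sign, and 25 of 73 calls of named genes were lost. Of 508 such calls 103 were lost with the replicate block and 134 with the length and GC trend removed, and 98 of 451 at 5% mitochondrial UMIs. With copied barcodes removed 74 of 501 were lost. With genes sharing sequence left out γδ T cells had 13. With the length and GC trend removed the counts were 1795 over all cells, 60 in CD4, 671 in CD8, 349 in NK, 1175 in T and 333 in cDC2. They were 177 in endothelial, 8 in γδ, 2007 in mesenchymal, 1117 in monocyte/macrophage and 399 in regulatory T cells, with 1 list called in γδ T cells. Fry called 39 lists in all, 3 in T cells, 2 in cDC2, 2 in endothelial cells, 0 in γδ T cells, 2 in mesenchymal cells and 1 in neutrophils. Camera with an estimated correlation called 0 lists in all, 0 in each of the 12 fits and the interferon list in 0, with 20 at an unadjusted p under 0.05.

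With each library left out in turn, 41 (24JK replicate 1) to 118 (24JK-FLT3L replicate 4) calls of named genes were lost. The gene counts ran from 1470 to 6107 over all cells, 683 to 1589 in CD8 T cells, 440 to 644 in NK cells, 1199 to 2228 in T cells and 433 to 1079 in cDC2. They ran from 307 to 714 in endothelial cells, 0 to 13 in neutrophils, 443 to 721 in regulatory T cells, 101 to 183 in CD4 T cells and 11 to 27 in γδ T cells. The lists called ran from 1 to 4 in NK cells, 0 to 3 in γδ T cells and 3 to 8 in CD8 T cells, and Flt3l over all cells ran from -0.64 to -0.43. The shares ran from -3.85 to -3.08 for CD4, 10.1 to 15.2 for CD8, -6.75 to -3.91 for regulatory T, -0.349 to 0.478 for γδ T cells and 10.7 to 17.4 for cDC2 among DCs. Those of classes ran from -9.10 to -2.59 for T cells, 8.60 to 16.4 for mesenchymal cells, -0.311 to -0.190 for pDC, -0.0121 to 0.126 for keratinocytes and 3.93 to 5.997 for monocytes and macrophages.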

Other observations

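The tests of explanations here were chosen after the results had been seen. Endothelial cells, through which leukocytes enter a tumor, had lower MHC class II, interferon-gamma and chemokine lists in the libraries labelled 24JK-FLT3L. Free RNA made up as much as 37.8% of endothelial counts in a library, and genes of other cells had low medians there without passing camera (shared conventional DC genes -0.61, T and NK cytotoxicity -0.94). A contribution of other cells to the lists below thus stays open. MHC class II presentation had 0 of 9 members called (5 lower adjusted over the list alone; median -0.72, adjusted p = 0.000287, and adjusted p = 0.483 with an estimated correlation). Interferon-gamma response genes had 4 of 19 lower (9 over the list alone; adjusted p = 0.000642, and adjusted p = 0.498 with an estimated correlation), with Serpina3g (-0.68), Igtp (-0.55) and Ly6a (-0.51). T cell-attracting chemokines had 0 of 5 called (2 over the list alone; adjusted p = 0.0159, and adjusted p = 0.483 with an estimated correlation). MHC class I presentation had 4 lower and 1 higher of 18 (adjusted p = 0.00391, and adjusted p = 0.583 with an estimated correlation), with Tapbp (-0.57) and Pdia3 (0.39), but not with a length and GC trend removed (adjusted p = 0.168).

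In cDC2, cytotoxicity genes, which mark lymphocytes, were lower (1 of 8, 4 adjusted over the list alone; adjusted p = 0.000642, and adjusted p = 0.231 with an estimated correlation), the called member being the cytokine gene Tnf (-0.88). Immediate early genes of the dissociation stress list passed camera as lower in 8 of 11 classes, with few members called in each, and with a length and GC trend removed in 4. CD8 T cells had 2 of 16 lower (7 over the list alone; adjusted p = 0.000203, and adjusted p = 0.425 with an estimated correlation). CD4 T cells also had 2 of 16 (4 over the list alone; adjusted p = 0.00275, and adjusted p = 0.425 with an estimated correlation). Monocytes and macrophages had 4 of 16 (5 over the list alone; adjusted p = 0.00717, and adjusted p = 0.584 with an estimated correlation). In cDC2 there were 3 of 16 (6 over the list alone; adjusted p = 3.33e-05, and adjusted p = 0.483 with an estimated correlation). Endothelial and mesenchymal cells had 1 of 16 each (adjusted p = 0.00379 and adjusted p = 0.0476, and adjusted p = 0.568 for both with an estimated correlation). γδ T cells had 1 of 13 (4 lower and 1 higher over the list alone; adjusted p = 0.0436, and adjusted p = 0.515 with an estimated correlation). Jund, an AP-1 subunit, fell in NK cells (-0.84), cDC2 (-0.78), CD8 T cells (-0.65), CD4 T cells (-0.54) and monocytes and macrophages (-0.49). In neutrophils interferon-gamma response genes had 2 of 15 lower (5 over the list alone; adjusted p = 0.000222, and adjusted p = 0.483 with an estimated correlation).

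The change was shared between cell classes: across 6305 genes tested in 6 classes, fold changes correlated between pairs of classes at r from 0.515 to 0.7999 (median 0.684, across genes), and 46.1% of genes had 1 sign in all 6. As high a median r came from 1 of 100 splits, the real one. The highest values in the other splits were a median r of 0.593 and 41.5% of genes with 1 sign. Transcript length and GC content do not account for it as the whole cause, because the median covariance between classes was 0.0374 after their removal (0.0571 before), above the 0.0269 of the highest other split. Free RNA is argued against by the 25% of genes with the least of it, where the median covariance was 0.0578, against 0.0579 over all genes. The median r was 0.739 there and 0.673 over all genes in the same fit, but r also moves with sampling noise. Library batch and the label cannot be told apart, as 0 series of library names hold libraries of both labels. A candidate explanation of a common exposure of all classes, technical or biological, stays open.

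As many changed genes as with the real labels came from 1 of 100 splits, the real one, in each of the 11 classes. No other split drawn thus reached the count, but the margin was small in neutrophils. Their 10 genes stood against 7 in another split, and fell to 4 with the copies removed and to 0 by edgeR without 24JK-FLT3L replicate 2, 3 or 4. The highest other splits called 6 genes in NK cells (667 with the labels), 6 in T cells (1814), 37 in cDC2 (692), 43 in endothelial cells (640) and 1424 in mesenchymal cells (3038). They called 120 in monocytes and macrophages (1927), 7 in neutrophils (10), 6 in CD4 T cells (165), 2 in CD8 T cells (1086), 5 in γδ T cells (25) and 7 in regulatory T cells (740). Over all cells 3 of 100 splits, the real one included, called at least the 2736 genes of the real one, and 1 of them called 4807. Splits other than the labels can thus give as many genes there, and the cause was not tested. Of the gene lists 76 were called in all, and 10 of 100 splits called as many (highest 101, median 40), so chance is not excluded for that total.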
